A study of Mus musculus with 6 samples.

How the data were processed

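Whole-heart RNA of 6 mice was sequenced, 3 wild-type (WT2368, WT2379 and WT2378) and 3 named SRAKO (SRAKO2365, SRAKO2371 and SRAKO2372), all given isoproterenol for 4 weeks per the series design text. The labels' protocols name oligo(dT) beads, which bind poly(A) RNA. Groups were taken from the sample titles. The titles carry a different number for each heart. Nothing in the labels says outright that the hearts came from separate animals or litters. The p-values of single rows therefore measure the spread between these samples. The labels give no sex, litter, batch or day.

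The authors deposited FPKM values per gene for each heart in a single table. FPKM is read coverage scaled by transcript length and library size, so it is not a count and the reads behind each value were not analysed here. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR were used, with no version given for edgeR. The same notes name the human build hg38, while the identifiers in the table are those of mouse genes. Of the 82368 transcript identifiers in the table, 98.3% matched the mouse annotation GENCODE M21 on GRCm38. Positions printed here come from that annotation through the transcript identifiers, because the table gives no coordinates. The build the authors aligned to is therefore open.

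The table holds 25901 rows, of which 16365 carry an Ensembl gene identifier and 9536 a locus assembled by StringTie. An assembled locus can merge neighbours: 492 rows carry more than 1 symbol and 66 carry none. Such rows are named by all their symbols at first mention. Without strand information in the labels, reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as Hspa1a and Hspa1b can share reads.

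Depth was recovered in part from the lowest values. FPKM of the weakest RNAs, multiplied by their length, rose in steps that were read as 1 aligned base. Of 47 to 62 low RNAs per heart, 57.1% to 73.5% fell on whole steps within 0.05, and the rest did not. The step was picked from values shared among these same RNAs, so part of that agreement was fixed in advance. Read as StringTie's scaling by all aligned bases, an FPKM of 1 stands for 8297, 11763 and 10128 aligned bases per kilobase in WT2368, WT2379 and WT2378, and for 12508, 10851 and 13098 in SRAKO2365, SRAKO2371 and SRAKO2372. These steps are bases and not whole reads, so no count test was run. Some zeros in the table are doubtful: 20 tested rows hold an exact 0 in at least 1 heart, and 13 of them reach an FPKM of 3 in another.

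Tests were run on log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Rows with an FPKM of at least 1 in at least 3 of the 6 hearts were kept, which left 10201. Each was fitted by genotype alone with a variance trend on the mean, a prior of 3.69 degrees of freedom and a two-sided moderated test. Benjamini-Hochberg adjustment ran over all tested rows with a threshold of 0.05. Log2 differences are SRAKO minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Sra1 was also tested with an exact permutation test.

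Gene lists suited to isoproterenol-treated heart and to loss of a steroid receptor coactivator RNA were fixed before the data were examined, 62 in all, including markers of the other cell types a heart sample can hold. A symbol found in several rows was taken from the row with the highest mean. Lists with at least 4 tested members, 53 of them, were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted by Benjamini-Hochberg over lists. At that value camera sets members against the other tested genes and treats them as nearly independent. Its p-values for lists and pathways rest on the spread between genes and do not by themselves measure the spread between hearts. The same lists were tested with a correlation estimated from the data and with fry. For each list the members were also adjusted over the list alone.

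Genes named in the text followed a rule also fixed before the data were examined. It takes Sra1, 12 rows per direction with a symbol that is not a predicted model and no overlap between genotypes, up to 4 members of a list with the smallest p, and Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn, Atp2a2 and Adrb1 whatever their values. Rows past the threshold come first among the 12, and the remaining places go to the smallest unadjusted p. Genes outside the rule are named where single hearts, the second Slc8a1 row and the pathway annotation are described.

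The code was tested on simulated data built from the 10201 rows of SRAKO against WT. Over 20 draws, limma called 25.5% of rows changed 1.5-fold, 67.9% of those changed 2-fold, 91.7% of those changed 4-fold and 96.3% of those changed 8-fold, and 0.06% of unchanged rows. A list shifted by 0.30 on the log2 scale was called by camera in 50 of 50 draws, against 0.96% of the unshifted lists. Noise was drawn independently for each gene in these simulations. In the hearts the estimated correlation was 0.43 for collagens and 0.95 for neutrophil markers. The 0.96% therefore does not carry over to the lists tested here.

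Alternatives fixed before the data were examined covered the pseudocount, the filter on low values, scaling between hearts, the variance model, weights per heart, summing of rows that share a symbol, and leaving out each heart in turn. Those chosen after seeing the data left out WT2368 and SRAKO2371, used the same pair as a batch term, or rescaled FPKM without mitochondrial and ribosomal RNA loci. Fits to counts by DESeq2 were not run because the table holds none. Every heart and every FPKM column was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.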

Results

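RNA abundance was measured in hearts of 3 wild-type mice and 3 SRAKO mice after 4 weeks of isoproterenol, a beta-adrenergic agonist that enlarges the heart. SRA is the steroid receptor RNA activator, a transcript of the gene Sra1 that acts as a coactivator of nuclear receptors and also encodes a protein. The comparison asks which cardiac transcripts differ with loss of SRA under this stimulus. Untreated hearts were not analysed here, so the response to isoproterenol itself was not measured. An FPKM of 1 stood for 8297 to 13098 aligned bases per kilobase, as far as the steps between low values show it. All 6 hearts had the expression pattern of males, with Xist at an FPKM of at most 0.0145 and Ddx3y between 2.14 and 3.17.

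Sra1 was lower in each SRAKO heart than in any WT heart. Mean FPKM was 4.98 ± 1.15 in WT and 1.93 ± 0.139 in SRAKO (SD, n = 3 each), 38.8% of WT. WT2368, WT2379 and WT2378 had 4.40, 6.31 and 4.23, and SRAKO2365, SRAKO2371 and SRAKO2372 had 1.96, 1.78 and 2.05. The log2 difference was -1.01 with an SE of 0.14, and it missed the threshold of limma after Benjamini-Hochberg adjustment (adjusted p = 0.258). An exact two-sided permutation test gave p = 0.1, the smallest that 3 hearts against 3 allow. The row spans chromosome 18 from 36666681 to 36679366 on the minus strand of GRCm38 and joins 5 transcripts of Sra1 (36666681 to 36670815) with 1 of the neighbouring gene Apbb3 (36671154 to 36679366). The remaining signal in SRAKO hearts can therefore not be assigned to Sra1, and the labels do not say which part of the gene was removed.

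Apc and Pafah1b1 fell in SRAKO hearts, and no row passed the threshold as higher. Apc, a negative regulator of Wnt signalling that marks beta-catenin for destruction, had a mean FPKM of 1.55 ± 0.125 in WT and 0.161 ± 0.0714 in SRAKO (SD, n = 3 each), 10.3% of WT. Its log2 difference was -1.14 with an SE of 0.09 (limma, Benjamini-Hochberg adjusted p = 0.0143). Apc lies on chromosome 18 from 34220924 to 34322552 on the plus strand, 2.45 Mb from Sra1. Pafah1b1, which encodes the dynein regulator LIS1, went from 7.79 ± 0.516 to 3.12 ± 0.165, a log2 difference of -1.09 with an SE of 0.09 (limma, Benjamini-Hochberg adjusted p = 0.0143). It lies on chromosome 11 from 74673949 to 74724670 on the minus strand. Both genes were lower in 3 of 3 SRAKO hearts than in any WT heart.

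Of the 10201 rows tested, limma with Benjamini-Hochberg adjustment called 2, both lower in SRAKO, and 0 higher. At an unadjusted p under 0.05 there were 353 rows, 194 higher and 159 lower, where chance alone gives 510.05. This number depended on the fit: it ran from 206 without SRAKO2372 to 683 without WT2368, and was 675 with array weights. The genotypes did not overlap in 821 rows, 8.05% of those tested, where chance gives 10%. Leaving out WT2368 or any of the SRAKO hearts ended both calls, and the number of rows called ranged from 0 to 7 when each heart was left out in turn. The log2 differences kept their size in these fits, from -1.19 to -1.10 for Apc and from -1.12 to -1.05 for Pafah1b1. WT2368 and SRAKO2371 carried more ribosomal RNA than the other hearts, and 0 rows were called without that pair of hearts (672 at an unadjusted p under 0.05; Apc -1.11 and Pafah1b1 -1.09) or with it as a batch term (407; -1.14 and -1.09).

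**Figure D1:**
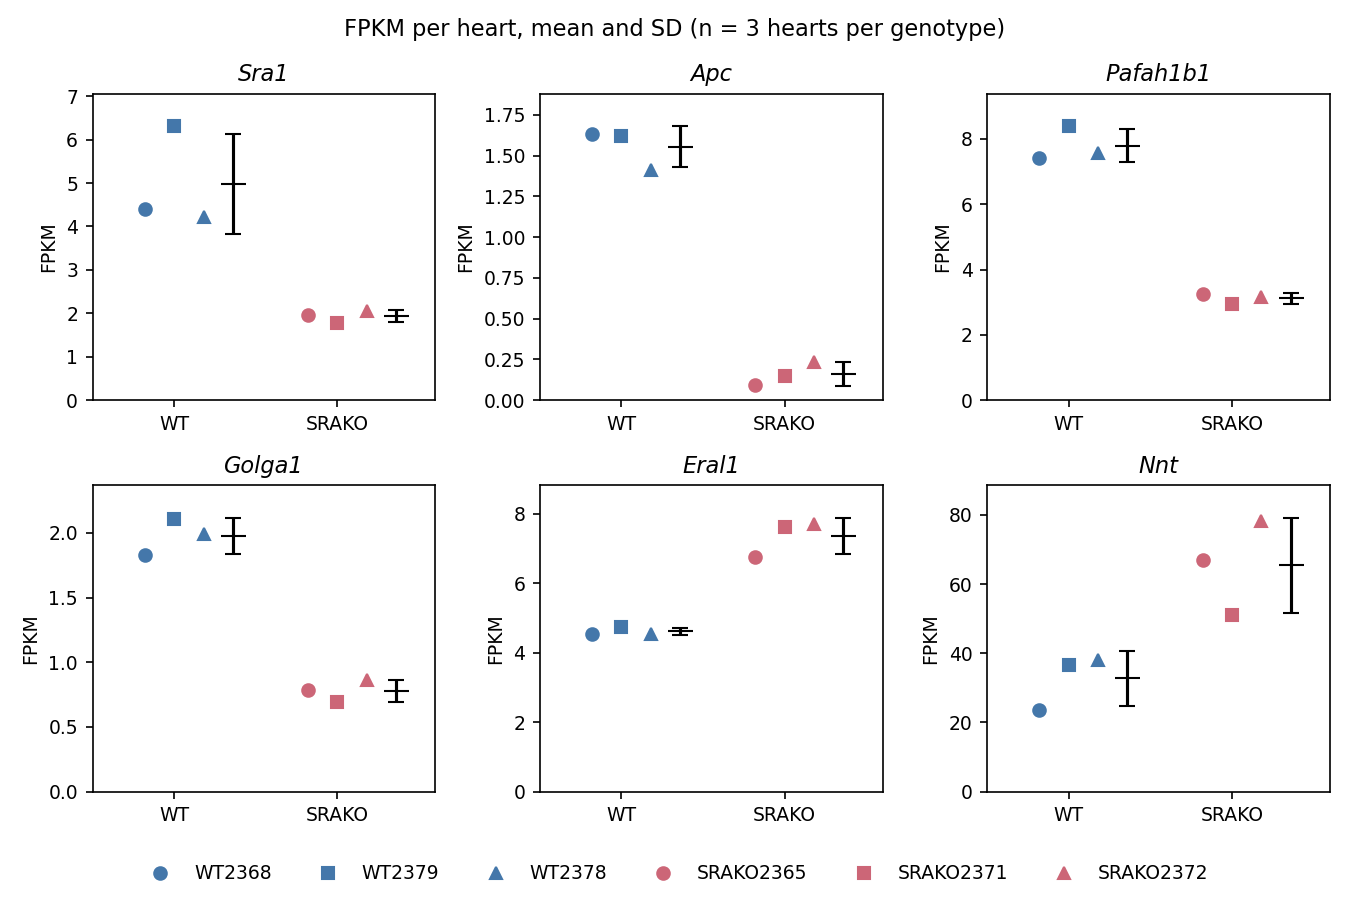
FPKM (vertical axes) of 6 genes in each WT (blue) and SRAKO (red) heart, with the mean and SD of 3 hearts beside the points. Sra1, Apc, Pafah1b1 and Golga1 lie lower in all 3 SRAKO hearts and Eral1 and Nnt higher, and of these Apc and Pafah1b1 pass the adjusted threshold.

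Among the rows with the smallest p that did not pass, Golga1, a golgin of the trans-Golgi network, came closest. Its mean FPKM was 1.98 ± 0.139 in WT and 0.780 ± 0.0849 in SRAKO (limma, Benjamini-Hochberg adjusted p = 0.114). Slc8a1, the sodium-calcium exchanger of the cardiomyocyte membrane, was listed in a row at 22.6 ± 3.69 in WT and 12.1 ± 3.02 in SRAKO, a log2 difference of -0.86. A second and stronger row of the same gene, named outside the rule, was at 58.1 and 48.2, a difference of -0.24. Log2 differences of the other lower rows were -1.03 for Mid1, -0.74 for Mir133a-1, -0.69 for AA672651, -0.54 for Mrps21, -0.50 for Naa25, -0.48 for Hipk2 and -0.47 for Mlx. Mir133a-1 is a microRNA precursor whose short row in a poly(A) library is hard to quantify. Apart from Golga1 and Sra1, each of these had an adjusted p of 0.999.

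Eral1, a chaperone of the mitochondrial ribosome's small subunit RNA, was the row nearest to a higher call, at 4.61 ± 0.114 in WT and 7.35 ± 0.525 in SRAKO (log2 difference 0.57; limma, Benjamini-Hochberg adjusted p = 0.526). Nnt, the nicotinamide nucleotide transhydrogenase of the inner mitochondrial membrane, shares its row with AC154550.1 and had 32.8 ± 7.99 in WT and 65.4 ± 13.8 in SRAKO, a difference of 0.98. Further log2 differences were 0.68 for Mmp28, 0.56 for Cytl1, 0.55 for Arrdc2, 0.53 for Tab2, 0.53 for the enkephalin precursor Penk and 0.46 for Pth1r. They were 0.43 for Slc7a8, 0.42 for Slc46a3, 0.37 for AC167229.2 and 0.35 for Rhd. All of them were higher in 3 of 3 SRAKO hearts, which the rule for naming them required. Save Eral1, each had an adjusted p of 0.999.

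Classic markers of hypertrophy differed by less than the spread between hearts. Nppa, the atrial natriuretic peptide, had a mean FPKM of 3565 ± 2639 in WT and 2229.8 ± 347 in SRAKO, and the WT mean rested on WT2379 at 6576. Nppb was at 97.3 ± 33.4 and 93.7 ± 11.9. The alpha and beta myosin heavy chains Myh6 and Myh7 (in a row with Mir208b) were at 2600.2 ± 180.4 against 2611 ± 119 and at 25.2 ± 0.380 against 27.2 ± 5.93. Skeletal alpha-actin, Acta1, was at 99.3 ± 42.9 and 89.2 ± 39.97. The calcium pump Atp2a2 was at 1346 ± 209 and 1361 ± 61.7, and the beta-1 adrenoceptor Adrb1 at 2.35 ± 0.586 and 2.31 ± 0.130. None of these genes passed limma's test with Benjamini-Hochberg adjustment (adjusted p of at least 0.999 for each), and of the 19 tested genes of the hypertrophy and fetal list 14 were lower and 5 higher. For that list, camera gave an adjusted p of 0.171 with a median log2 difference of -0.21, and 1 member, Xirp2 (21.4 ± 4.75 against 15.9 ± 1.07), had an unadjusted p under 0.05.

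**Figure D2:**
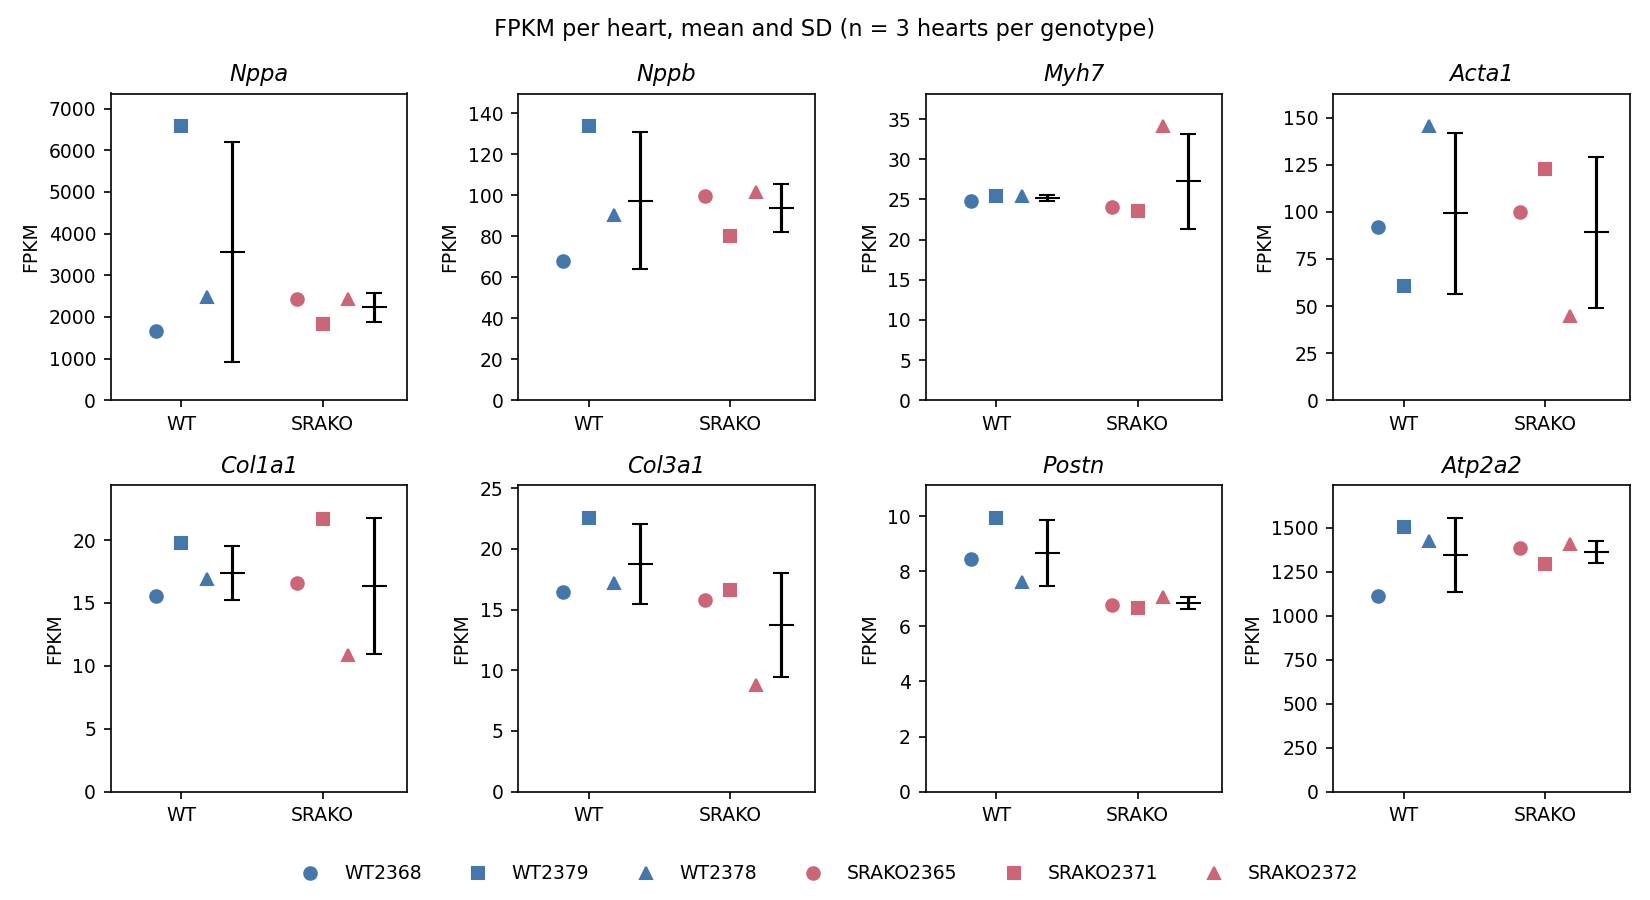
FPKM (vertical axes) of 8 hypertrophy, fibrosis and calcium handling genes in each WT (blue) and SRAKO (red) heart, with the mean and SD of 3 hearts. Nppa reaches 6576 in WT2379 and stays at or below 2469 in the other hearts, and none of the genes passes the adjusted threshold.

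The list of collagens and extracellular matrix was lower in SRAKO, with 32 of its 39 tested genes below WT. The median log2 difference was -0.15 (camera, Benjamini-Hochberg adjusted p = 7.75e-05, but adjusted p = 0.969 with an estimated correlation). Postn, the matricellular protein periostin, had 8.66 ± 1.18 in WT and 6.84 ± 0.212 in SRAKO. Sparc was at 133 ± 8.16 and 104 ± 19.7, the prolyl hydroxylase P4ha1 at 8.99 ± 1.57 and 7.03 ± 0.459, and Col5a2 at 5.37 ± 0.910 and 4.25 ± 0.331. Col1a1 differed little, at 17.4 ± 2.16 and 16.4 ± 5.40, and Col3a1, in a row with AC125167.1, was at 18.7 ± 3.32 and 13.7 ± 4.31. Of the 39 members 0 passed adjustment over all rows and 0 adjusted over the list alone (limma, Benjamini-Hochberg), and 3 had an unadjusted p under 0.05, all lower. Without WT2379 the median was -0.06 and the list was no longer called.

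Across the 53 lists tested, camera with the preset correlation called 12, of which 7 were higher and 5 lower in SRAKO. With a correlation estimated from the data 0 lists were called (smallest adjusted p = 0.969; 1 list, the SRA partners, at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.999). The adjusted 0.969 was shared by all 53 lists and so does not rank them. Among the 12 called lists the unadjusted camera p with an estimated correlation ran from 0.0436 (SRA partners) to 0.548 (ribosomal proteins). In these 12 lists no member passed Benjamini-Hochberg adjustment in limma, whether over all rows or adjusted over the list alone.

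Known protein partners of SRA and nuclear receptor coregulators were lower, 17 of 18, by a median of -0.11 (camera, Benjamini-Hochberg adjusted p = 0.000564, but adjusted p = 0.969 with an estimated correlation). The RNA helicase Ddx17 had a mean FPKM of 17.8 ± 0.253 in WT and 15.2 ± 1.297 in SRAKO, and Ctcf 4.02 ± 0.225 and 3.47 ± 0.226. The corepressors Ncor1 and Spen were at 5.14 ± 0.651 against 4.39 ± 0.366 and at 2.42 ± 0.654 against 1.83 ± 0.262. No member had an unadjusted p under 0.05 (0 of 18). The list was not called with a filter at an FPKM of 5, which left 6 members (median -0.06), or without both WT2368 and SRAKO2371 (-0.09).

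Glucocorticoid-induced genes were higher, 18 of 20, by a median of 0.23 (camera, Benjamini-Hochberg adjusted p = 0.000111, but adjusted p = 0.969 with an estimated correlation). Fkbp5, an immunophilin that restrains the glucocorticoid receptor, had 9.58 ± 1.15 in WT and 13.5 ± 3.29 in SRAKO. Fam107a was at 7.69 ± 2.52 and 12.5 ± 3.55, Sult1a1 at 24.9 ± 2.59 and 31.0 ± 3.70, and Lcn2 at 1.43 ± 0.327 and 2.63 ± 1.301. Lcn2 is also among the neutrophil markers and was highest in SRAKO2372, at 4.09. At an unadjusted p under 0.05 there were 3 members, all higher. WT2368, 1 of the hearts with high ribosomal RNA, had the lowest values of the list, and without it the median was 0.11. The p53 and apoptosis list, which shares Cdkn1a with it, was also higher, 15 of 18 genes with a median of 0.12 (camera adjusted p = 0.0350, but adjusted p = 0.969 with an estimated correlation). Its examples were Trp53inp1 at 1.02 ± 0.0739 and 1.43 ± 0.0732, Cdkn1a at 23.1 ± 5.96 and 38.7 ± 17.8, Fas at 5.56 ± 0.126 and 6.51 ± 1.08, and Casp9 at 1.63 ± 0.0196 and 1.88 ± 0.233. With 1 heart left out its median ran from 0.06 to 0.14, and the list stayed called only without WT2368.

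Markers of white and brown fat were higher in 13 of 13 genes, by a median of 0.70 (camera, Benjamini-Hochberg adjusted p = 0.000267, but adjusted p = 0.969 with an estimated correlation). The excess sat mainly in SRAKO2371, where the median over the markers was 1.88 above the WT mean, against 0.55 in SRAKO2372 and -0.31 in SRAKO2365. Without SRAKO2371 the median difference was 0.15 and the list was not called, nor was it without WT2379. Pparg was at 4.22 ± 0.221 and 5.38 ± 1.13, the lipid droplet proteins Plin1 and Cidec at 0.916 ± 0.330 against 3.07 ± 2.70 and at 5.36 ± 1.999 against 13.6 ± 11.8, and Cidea at 19.8 ± 2.98 and 36.4 ± 24.1. The insulin and PPAR-gamma adipogenic list, which overlaps these markers, was higher in 17 of 19 genes by a median of 0.27 (camera adjusted p = 0.000959, but adjusted p = 0.969 with an estimated correlation). Lipe and Fabp4 were at 11.96 ± 1.74 against 16.1 ± 3.25 and at 92.3 ± 13.7 against 114 ± 16.96. Akt2, the insulin-responsive kinase, went the other way at 19.5 ± 4.35 and 12.8 ± 1.02, lower in 3 of 3 SRAKO hearts. Without SRAKO2371 this list had a median of 0.16 and was not called.

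Neutrophil markers had the largest median of the called lists, 1.59 over 5 genes, all higher (camera, Benjamini-Hochberg adjusted p = 0.000267, but adjusted p = 0.969 with an estimated correlation). Of the 12 markers fixed, only these 5 passed the filter, and the correlation estimated between them was 0.95. Without both WT2368 and SRAKO2371 their median was 1.24 and the list was not called. S100a8 had a mean FPKM of 0.571 ± 0.832 in WT and 4.70 ± 4.22 in SRAKO, S100a9 2.74 ± 3.30 and 17.9 ± 16.2, and Retnlg 0.550 ± 0.727 and 4.33 ± 3.90. The median over the markers lay 2.78 above the WT mean in SRAKO2372 and 1.99 above it in SRAKO2371, but 0.01 above it in SRAKO2365 and 0.81 above it in WT2379. Macrophage and monocyte markers were higher in 11 of 14 genes by 0.13 (camera adjusted p = 0.0350, but adjusted p = 0.969 with an estimated correlation). C1qa was at 29.5 ± 5.14 and 36.2 ± 1.71, C1qc at 18.5 ± 3.42 and 21.5 ± 0.906, Ly6c2 at 1.73 ± 0.474 and 2.29 ± 0.222, and Cd163 at 4.65 ± 0.166 and 5.37 ± 0.827. The macrophage list stayed called only without WT2379, with medians from 0.07 to 0.16 when 1 heart was left out. Interferon-stimulated genes were lower in 19 of 21, by -0.09 (camera adjusted p = 0.0180, but adjusted p = 0.969 with an estimated correlation). Bst2 was at 13.03 ± 1.67 and 10.6 ± 0.948 and Ddx58, the RNA sensor RIG-I, at 1.67 ± 0.212 and 1.37 ± 0.208. The median of the interferon-stimulated genes ran from -0.16 to -0.03 with 1 heart left out, where the call held only without WT2379 or SRAKO2365, and camera pointed higher without both WT2368 and SRAKO2371.

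**Figure D3:**
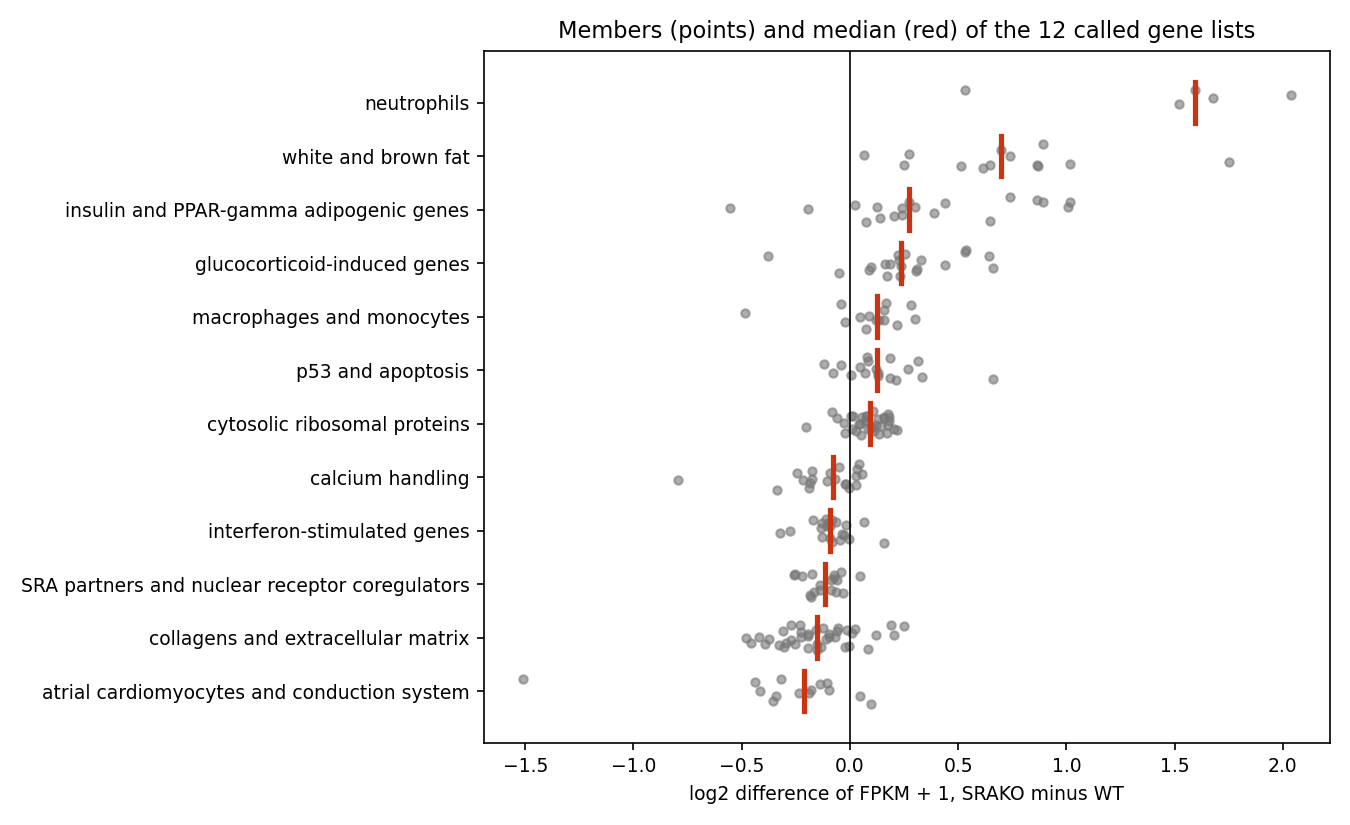
Log2 difference of FPKM + 1, SRAKO minus WT (horizontal axis), of each tested member (grey points) and the median (red line) of the 12 gene lists that camera called with a preset correlation. Medians run from -0.21 for atrial markers to 1.59 for neutrophil markers, and no list is called with an estimated correlation.

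Atrial and conduction system markers were lower in 12 of 14 genes, by a median of -0.21 (camera, Benjamini-Hochberg adjusted p = 0.00153, but adjusted p = 0.969 with an estimated correlation). The atrial potassium channels Kcnj3 and Kcnj5 were at 3.37 ± 0.138 against 2.32 ± 0.665 and at 11.2 ± 1.02 against 8.75 ± 1.07, Stard10 at 21.9 ± 4.25 against 16.9 ± 3.26, and Bmp10 at 148 ± 91.3 against 74.6 ± 62.6. WT2379 held the highest Nppa and Myl7 of all hearts, and without it the median of the atrial list was 0.01 and the list was not called. Calcium handling genes were lower in 15 of 20, by -0.08 (camera adjusted p = 0.00474, but adjusted p = 0.969 with an estimated correlation). The calcium channel subunit Cacnb2 had 3.33 ± 0.871 and 2.39 ± 0.353, Itpr1 1.2996 ± 0.0160 and 1.03 ± 0.145, and the ryanodine receptor Ryr2 36.5 ± 2.05 and 32.2 ± 2.68. Cytosolic ribosomal proteins were higher in 31 of 36 genes by 0.09 (camera adjusted p = 0.0229, but adjusted p = 0.969 with an estimated correlation), with Rps6 at 71.5 ± 7.60 and 80.9 ± 3.12. Without WT2368 their median was -0.01, and without both WT2368 and SRAKO2371 it was -0.07.

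The other 41 tested lists were not called, with adjusted p from 0.0518 to 0.934 in camera. Smooth muscle and pericyte markers came closest (13 of 15 higher, median 0.08), led by Myh11 at 11.98 ± 2.14 and 16.2 ± 0.804. Oxidative stress and NRF2 targets followed with an adjusted p of 0.0777 and a median of 0.11 (15 of 21 higher and 6 lower; 3 higher and 1 lower at an unadjusted p under 0.05). Among them Ucp2 was at 16.1 ± 3.28 and 21.8 ± 1.35, Gsta4 at 38.1 ± 0.218 and 46.0 ± 2.01, and Txnrd1, the lower one, at 5.81 ± 0.870 and 4.61 ± 0.270. The heat shock list had the same adjusted p and a median of -0.02, and Hspa1a and Hspa1b stood apart in it at 10.3 ± 6.84 against 1.66 ± 0.408 and at 10.5 ± 7.42 against 1.64 ± 0.0766. Hspa1a was at 14.5 and 13.9 in WT2368 and WT2379 but at 2.37 in WT2378, and both passed limma with Benjamini-Hochberg adjustment only without WT2378 (log2 difference -2.52, adjusted p = 0.00471, for Hspa1a). Cell cycle genes had 4 of 6 lower with a median of -0.13, including Ccnd2 at 7.89 ± 0.895 and 6.25 ± 0.871. Ion channels had 12 of 23 higher, with 3 lower and 1 higher at an unadjusted p under 0.05. Among endocardial markers Cytl1 alone passed when adjusted over the list alone (1 of 7 genes, adjusted p = 0.0388), and 0 passed over all rows.

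Apart from the hypertrophy and fetal list given above (-0.21), the cardiac programmes among the uncalled lists had medians of -0.03 for the sarcomere, -0.02 for beta-adrenergic signalling, 0.04 for ventricular cardiomyocytes, -0.01 for calcineurin, NFAT and MEF2, and 0.00 for ion channels. In energy metabolism the medians were 0.01 for fatty acid oxidation, 0.01 for glycolysis and glucose uptake, 0.03 for the TCA cycle, 0.04 for nuclear-encoded oxidative phosphorylation and 0.03 for mitochondrially encoded genes. Signalling lists gave 0.04 for TGF-beta, -0.04 for Wnt, 0.02 for MAPK, -0.00 for PI3K, AKT and mTOR, 0.00 for angiogenesis and hypoxia, and 0.01 for nuclear receptors. Stress and turnover lists gave -0.06 for the unfolded protein response, 0.07 for the integrated stress response, 0.06 for autophagy, -0.00 for atrophy and the proteasome, -0.02 for immediate early genes, -0.04 for the circadian clock, 0.00 for splicing factors, and 0.05 for imprinted genes and long noncoding RNAs. Immune lists gave -0.09 for antigen presentation, 0.03 for cytokines and -0.12 for B and plasma cells.

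Stromal and vascular marker lists were not called either. Their medians were 0.06 for fibroblasts, -0.09 for activated fibroblasts, 0.03 for endothelial cells, -0.03 for lymphatic endothelium, -0.01 for endocardium, 0.11 for valve and cartilage-like cells, -0.28 for erythroid cells and -0.09 for sex-linked genes. The camera direction was opposite to the median for ion channels, ventricular cardiomyocytes, immediate early genes, splicing factors, angiogenesis, nuclear receptors, the integrated stress response, cytokines and the genes around Sra1. Under the minimum of 4 tested members, 9 lists had no test. T and NK cells, mast cells, platelets, mesothelium, Schwann cells, skeletal muscle and liver proteins had 1 to 3 tested members each, with medians of -0.21, 0.19, 0.23, -0.20, -0.14, -0.12 and 0.02, and lung and thymus had 0.

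Genes around Sra1 on chromosome 18 were not shifted as a list (20 tested, 9 higher and 11 lower, median -0.01, camera adjusted p = 0.918). Ankhd1, in a row with Eif4ebp3, had 2.92 ± 0.211 in WT and 2.28 ± 0.238 in SRAKO, and Diaph1, a formin that nucleates actin, 3.49 ± 0.820 and 4.59 ± 0.104. Zmat2 was at 11.2 ± 0.857 and 12.8 ± 0.389, and Igip at 1.64 ± 0.315 and 1.97 ± 0.281. Within 5 Mb of Sra1 on either side, 69 other genes were tested, of which 7 had an unadjusted p under 0.05, 4 lower and 3 higher.

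**Figure D4:**
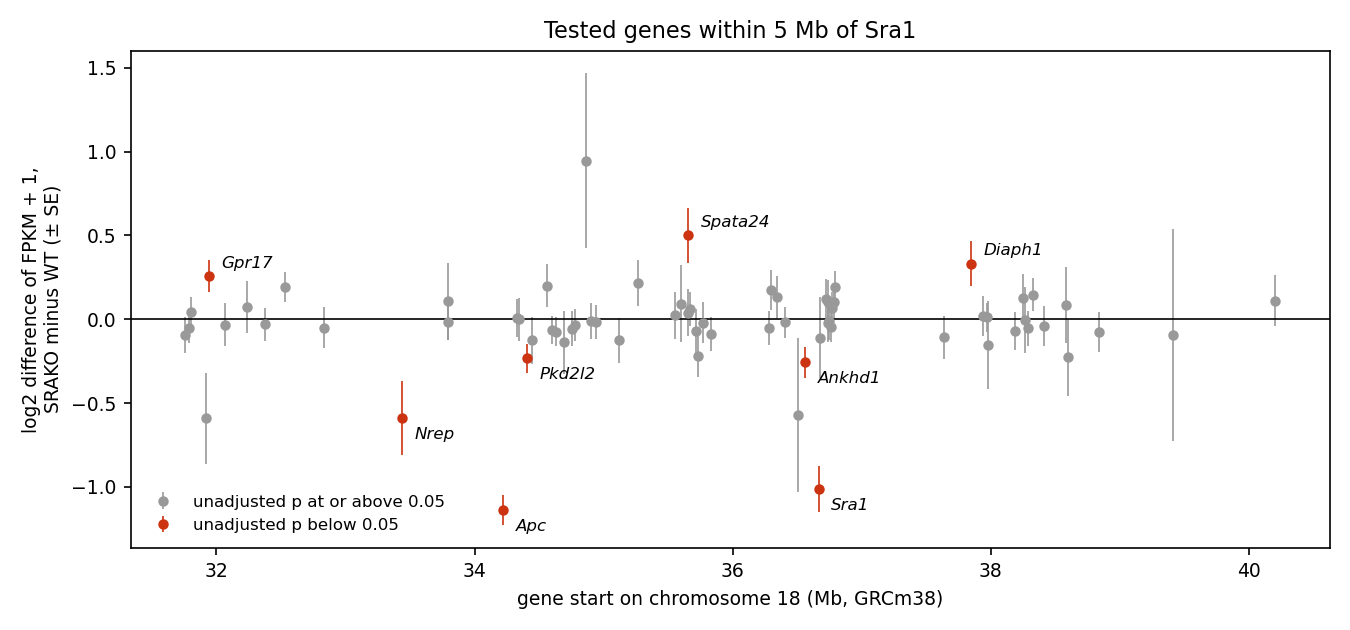
Log2 difference of FPKM + 1, SRAKO minus WT, with its SE (vertical axis), of Sra1 and the 69 other tested genes within 5 Mb of it, by gene start on chromosome 18 in GRCm38 (horizontal axis, Mb). Apc at -1.14 and Sra1 at -1.01 lie below the rest, and red points have an unadjusted p below 0.05.

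Some hearts stood apart within their genotype. The ribosomal RNA locus AY036118 (in a row with CT010467.1) had an FPKM of 6242 in WT2368 and 3003 in SRAKO2371, against 273 to 595 in the other hearts. The mitochondrial ribosomal RNA mt-Rnr1 was at 4548 and 1896 in the same pair and at 879 to 1122 elsewhere. The first principal component, with 37.7% of the variance, separated WT2368, and the second, with 22.8%, separated SRAKO2371. Adipoq, the adipocyte hormone adiponectin, was at 17.5 in SRAKO2371 and between 2.93 and 7.17 in the others. Correlations of log2 values across genes, which are not independent replicates, were 0.969 to 0.985 within a genotype and 0.971 to 0.988 between genotypes.

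**Figure D5:**
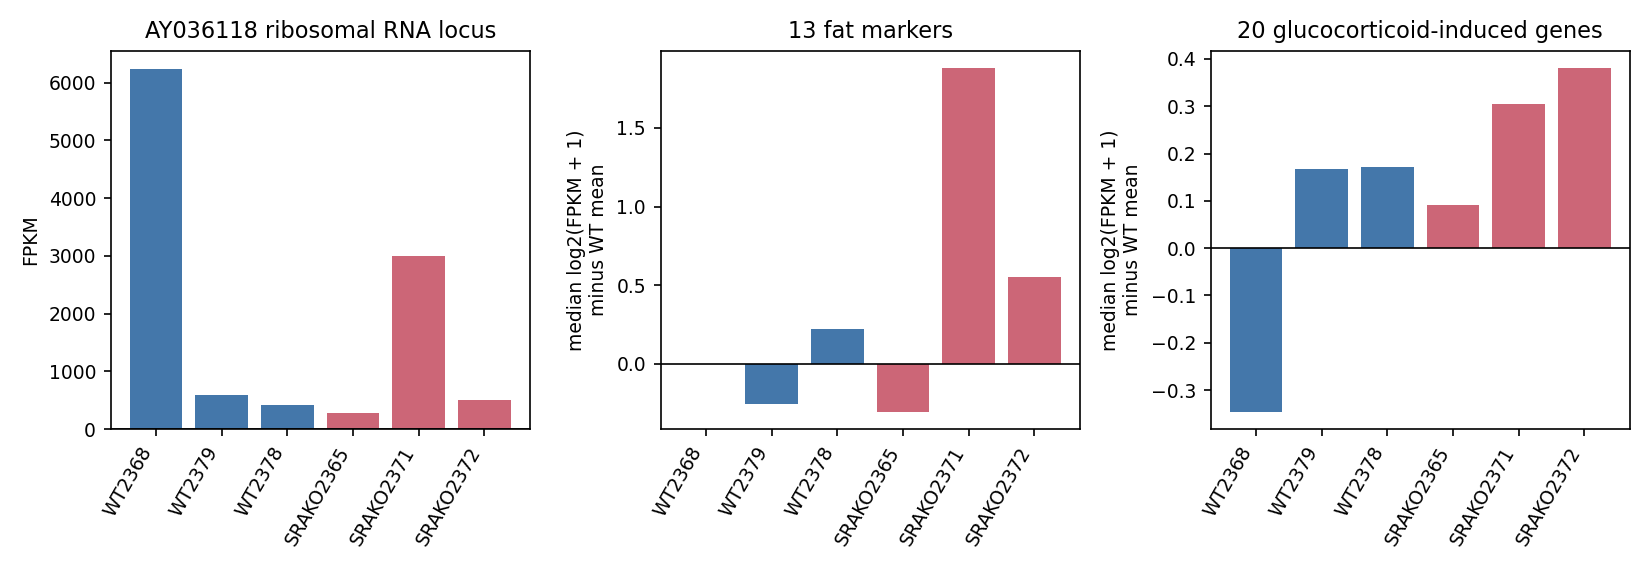
Values per heart, WT in blue and SRAKO in red: FPKM of the AY036118 ribosomal RNA locus, and the median over fat markers and over glucocorticoid-induced genes of log2(FPKM + 1) minus the WT mean (vertical axes). Ribosomal RNA is highest in WT2368 (6242) and SRAKO2371 (3003), fat markers in SRAKO2371 (1.88), and the glucocorticoid-induced genes are lowest in WT2368 (-0.35).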

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

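Leaving out WT2368 and SRAKO2371, using that pair as a batch term and rescaling without mitochondrial and ribosomal RNA loci were chosen after seeing the data. Sra1 stayed lower and short of the threshold in 19 of 19 settings, from -1.30 to -0.86 (limma, Benjamini-Hochberg adjusted p from 0.101 to 0.886). Apc and Pafah1b1 stayed lower throughout, and each lost its call in 8 settings. For Apc these were a pseudocount of 0.1 (-2.70), no filter (-1.14), the batch term (-1.14), leaving out both hearts (-1.11) and 4 of the fits that left out 1 heart (-1.19 to -1.10 over all 6). For Pafah1b1 they were TPM (-1.18), no filter (-1.09), the batch term (-1.09), leaving out both hearts (-1.09) and 4 of the fits that left out 1 heart (-1.12 to -1.05). Against 2 genes called by limma, 1 was called with a pseudocount of 0.1, a filter at an FPKM of 5 or TPM. With no filter 0 of 25901 were called (919 at an unadjusted p under 0.05), and 0 without both hearts or with the batch term. Leaving out 1 heart gave 0 to 7 genes: 0 without WT2368 (683 at an unadjusted p under 0.05) or SRAKO2365 (409), 1 without SRAKO2371 (Rab12) or SRAKO2372 (Zfp46), 6 without WT2379 and 7 without WT2378. Hspa1a (-2.52 to -1.42 over the 6 fits) and Hspa1b (-2.57 to -1.34) were called without WT2378. These single-heart calls were named after their values were seen, and fewer hearts estimate the spread less precisely.

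Against 12 lists, 6 were called with a filter at an FPKM of 5, 6 without both hearts, and 6 to 15 when 1 heart was left out. With the batch term, and with rescaling without mitochondrial and ribosomal RNA loci, all 12 stayed called. The batch term holds 1 heart per genotype and so leaves each difference as it is, and the rescaling applies 1 factor per heart. Neither setting can therefore decide whether ribosomal RNA carry-over matters for these lists. Over the 12 lists 200 of 262 values kept direction and call. An estimated correlation and fry called 0 lists, with medians as before: -0.152 for collagens, 0.235 for glucocorticoid-induced genes, 1.59 for neutrophils, 0.698 for fat, -0.113 for SRA partners, 0.274 for insulin and PPAR-gamma, -0.213 for atrial markers, -0.0797 for calcium handling, -0.0901 for interferon-stimulated genes, 0.0909 for ribosomal proteins, 0.124 for p53 and 0.127 for macrophages. Without both hearts 3 of the 12 stayed called (collagens, calcium handling and atrial markers). The others lost the call at 0.107 for glucocorticoid-induced genes, 1.24 for neutrophils, 0.181 for fat, -0.0928 for SRA partners, 0.152 for insulin and PPAR-gamma, 0.0635 for p53 and 0.0837 for macrophages. Ribosomal proteins turned to -0.0673, and interferon-stimulated genes kept a median of -0.0285 while camera pointed higher; the cause was not tested. The filter at an FPKM of 5 ended the calls of SRA partners (-0.0627), ribosomal proteins (0.0909), p53 (0.119) and macrophages (0.146). TPM ended those of ribosomal proteins (0.1003) and macrophages (0.141), and no filter those of interferon-stimulated genes (-0.0717) and macrophages (0.103). Calls were also lost when 1 heart was left out, where medians ran from -0.275 to -0.0605 for collagens, 0.153 to 1.24 for fat, 0.165 to 0.403 for insulin and PPAR-gamma, -0.451 to 0.00870 for atrial markers, -0.156 to -0.0295 for interferon-stimulated genes, -0.00974 to 0.141 for ribosomal proteins, 0.0560 to 0.141 for p53 and 0.0712 to 0.165 for macrophages.

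Over 107 genes followed through the settings, 2051 of 2094 values kept direction and side of the threshold. Only 2 of these genes, Apc and Pafah1b1, were called in the main fit, so for the rest this mostly means staying uncalled. The 16 values that lost a call were 8 of 19 for Apc and 8 of 20 for Pafah1b1. Another 24 turned, and the cause was not tested. Myh6 turned to -0.00255 with upper quartile scaling, -0.00172 with median scaling, -0.0261 with array weights and -0.0269 without both hearts. Atp2a2 turned to -0.0627 with array weights and -0.0687 without both hearts. Adrb1 turned to -0.0107, -0.00870 and -0.00709 with upper quartile, median and quantile scaling, Nppb to 0.00204 with TPM, and Rtp4 to 0.137 without both hearts. Leaving out 1 heart gave -0.866 to 0.131 for Nppa, -0.237 to 0.248 for Nppb, -0.0514 to 0.0420 for Myh6, -0.0774 to 0.180 for Myh7, -0.488 to 0.246 for Acta1, -0.343 to 0.123 for Col1a1, -0.106 to 0.113 for Atp2a2, -0.141 to 0.116 for Adrb1 and -0.534 to 0.00956 for Rtp4. If the steps are read as aligned bases, an FPKM of 1 rests on 8297 to 13098 of them per kilobase. Genes under an FPKM of 1, such as Apc in SRAKO hearts (0.161), have differences that depend on the pseudocount. Fits to counts were not run because the table holds none.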

Other observations

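The pathway tests, the tests of genome position, the fits without both hearts high in ribosomal RNA, with them as a batch term or rescaled without ribosomal RNA, and the test for attached fat were chosen after the results they bear on were seen, while leaving out each heart in turn was fixed before. Enzymes of drug metabolism by cytochrome P450 were higher in SRAKO in 22 of 24 annotated genes, by a median log2 difference of 0.16. This was the smallest p of the 281 pathways annotated in the table with at least 10 tested genes (camera, Benjamini-Hochberg adjusted p = 0.000129, but adjusted p = 0.996 with an estimated correlation). The flavin monooxygenase Fmo1 had a mean FPKM of 8.50 ± 0.771 in WT and 11.2 ± 1.36 in SRAKO, and Fmo2 19.4 ± 2.10 and 25.7 ± 5.27. Gsta4, a glutathione transferase that clears the lipid peroxidation product 4-hydroxynonenal, was at 38.1 ± 0.218 and 46.0 ± 2.01, and Cyp2e1 at 9.96 ± 3.19 and 18.2 ± 9.59. The pathway was called without SRAKO2371 (adjusted p = 0.0201) but not without both WT2368 and SRAKO2371 (adjusted p = 0.119). In all, camera called 8 pathways with the preset correlation, 5 higher and 3 lower, and 0 with an estimated one. The adjusted p of 0.996 was the smallest of the 281 with an estimated correlation and does not rank the pathways.

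Protein digestion and absorption, a pathway made up largely of collagens and transporters, was lower in 24 of 31 genes by -0.14 (camera adjusted p = 0.0206, but adjusted p = 0.996 with an estimated correlation). It was the 1 called pathway that was also called in the same direction without WT2368 and SRAKO2371 (adjusted p = 0.00755). PPAR signalling was higher in 38 of 50 genes by 0.08, with Fads2 and Slc27a1 at its head (camera adjusted p = 0.0176, but adjusted p = 0.996 with an estimated correlation). Without SRAKO2371 its adjusted p was 0.601.

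Apc, 1 of the 2 genes called, lies 2.45 Mb from Sra1. Of 69 tested genes within 5 Mb of Sra1, 10.1% had an unadjusted p under 0.05. With Apc included, this was above 99.4% of 8499 overlapping windows of as many neighbouring genes on other chromosomes (median 2.90%). Without Apc it was 6 of 68 genes (8.82%), above the same 99.4% of windows and above their 95th percentile of 7.25%. Windows with 6 of 69 (8.70%), such as the richest on chromosomes 10, 16 and 19, counted as below it though they held as many. The richest windows elsewhere reached 11.6% on chromosome 17 and 10.1% on chromosomes 6, 11 and 14, and the richest on chromosome 18 (13.04%, from 6733905 to 34444116) holds Apc but lies mostly outside the 5 Mb. A segment of chromosome 18 carried along with the targeted allele could account for these genes, which only genotypes can settle. Apc reads that moved to another row were not seen in the row overlapping Apc, which rose by 0.0415 FPKM against 1.39 lost by Apc. The 3 rows without a position that rose by more than 0.697 FPKM are numbered among loci of chromosomes 4, 10 and 15. That numbering follows position for 93.0% of neighbouring loci. FPKM is scaled by length, so a loss and a rise in rows of unlike length cannot be set equal. Moved reads can therefore not be excluded. A difference in strain background beyond chromosome 18 cannot be told apart from an effect of the genotype, since 0 pairs of genes with an unadjusted p under 0.01 lay within 1 Mb of each other where shuffling gives a median of 1, a count too low to decide. Nnt on chromosome 13, higher by 0.98, falls under the same doubt, because part of that gene is missing in some C57BL/6 substrains and the labels name no strain. An effect of SRA on Apc stays open and untested.

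Fat markers were higher in SRAKO by a median of 0.70, mainly in SRAKO2371, where Adipoq reached 17.5. Without SRAKO2371 the median was 0.15, which restates that most of the excess sits in that heart, so fat attached to it cannot be told apart from an effect of the genotype that varies between hearts. Without both hearts high in ribosomal RNA the median was 0.18, a setting that also removes SRAKO2371, so carry-over of ribosomal RNA cannot be told apart either. The list stayed called at 0.70 with those hearts as a batch term and after rescaling without mitochondrial and ribosomal RNA loci, but the batch term holds 1 heart per genotype and so leaves the difference as it is, and the rescaling applies 1 factor per heart. Without WT2368 alone, the heart with the most ribosomal RNA, the median stayed at 0.70. SRAKO2372 also lay above the WT mean, by 0.55, and SRAKO2365 below it, by -0.31.

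Glucocorticoid-induced genes were higher in SRAKO by a median of 0.23. Without WT2368 the median was 0.11, just under 0.12, the limit set beforehand as a fixed share of the 0.23. WT2368 had the lowest values of the list, so leaving it out restates that much of the difference sits there. Low values in that library can therefore not be told apart from an effect of the genotype. Without both hearts high in ribosomal RNA the median was 0.11 as well, a setting that also lacks WT2368 and therefore cannot separate carry-over from other traits of that library. With the batch term and with the rescaling the list stayed called at 0.23 and 0.24, which decides nothing for the reasons given for fat, and SRAKO2371, also high in ribosomal RNA, lay above the WT mean (0.31) where WT2368 lay below it (-0.35). Different clock times of the genotypes cannot be told apart either: 6 clock genes differed by 0.20 on average without regard to sign, with a mean SE of 0.23. Dbp (-0.42), Nr1d1 (-0.40) and Per2 (-0.02) were lower, and Arntl (0.15), Npas2 (0.08) and Per3 (0.11) higher. Arntl and Npas2 did not pass the filter, with mean FPKM from 0.37 to 0.58, where log2(FPKM + 1) understates changes. An effect of SRA on glucocorticoid receptor targets stays open. Camera with the preset correlation still called the list without WT2368, but not without both hearts high in ribosomal RNA. With an estimated correlation camera did not call it in all 6 hearts (adjusted p = 0.969).

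With 3 hearts against 3 there are 10 splits, too few for a share under 0.05. The real split called 2 genes and the highest of the other splits 3, and 6 of the 10 splits called at least as many as the real one. For gene lists the real split called 12 and the others 2 to 18, and 4 of the 10 splits called at least as many as the real one.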
